A study of Homo sapiens with 13 samples.

How the data were processed

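Primary adult human hepatic stellate cells, grown untreated in DMEM with serum, were profiled by CUT&Tag for H3K4me3, H3K27ac and an IgG control (2 samples each), in which an antibody directs a transposase to marked chromatin, and by RNA sequencing of poly(A), rRNA-depleted, cytoplasmic, nuclear and long-read libraries. Groups were taken from the labels. Per the labels' protocols, short-read libraries used a strand-specific kit and long-read cDNA was sequenced on a PacBio instrument. The submitters' processing notes name Bowtie2, GATK, SEACR, FastQC 0.11.9 and minimap2, without roles, and the build GRCh38 (hg38). Other filters, the aligner of the short RNA reads and the use of the IgG samples in peak calling were not given in the sources used here. Nothing in the labels says whether replicates came from separate donors or cultures.

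The files used were 1 deposited peak list per mark, 1 deposited set of long-read transcript structures and 1 deposited set of lncRNA models. The deposited peak lists give start and end positions with no score or signal, and both replicates of a mark name the same list, so 1 list stands for 2 replicates and how they were combined is not given in the sources used here. The long-read file gives transcript and exon positions with no read counts. The lncRNA models, per the file headers, came from StringTie and carry deposited TPM values, which sum to 34978 over the models used. The set over which they were normalised is not given in the sources used here. All models were at least 200 bases long. The IgG, cytoplasmic, nuclear and rRNA-depleted samples were not analysed here. In all results only chromosomes 1 to 22 and X were used.

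Gene intervals came from the RefSeq gene table of GRCh38.p14, the build of the files, which has neither strand nor exons. A gene was therefore called marked when a peak lay within 1 kb of either end of its interval. Among 5323 genes over 5 kb whose strand long-read transcripts gave, H3K4me3 lay within 1 kb of the 5′ end in 91.9%, of the 3′ end in 5.88% and of the 3′ end alone in 25, and H3K27ac in 94.1%, 20.6% and 53. A locus was called annotated when at least 1 of its models carried an Ensembl transcript identifier. A long-read transcript was assigned, without regard to strand, to the annotated gene that held at least 1 of its exonic bases and the largest share of the joint span, and isoforms are the distinct transcript models of a locus in the file. The comparison of intron chains with annotated chains planned for the long reads could not be made with this table, and the overlap of loci with gene intervals was used instead.

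Overlaps needed at least 1 bp, and marks at starts a distance of at most 1 kb. Observed shares were set against 1000 circular shifts of positions within each chromosome, one-sided, which is a permutation of positions, with a smallest possible p of 0.001. Classes of loci or starts were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 8 tests of a family. Intervals are exact Clopper-Pearson intervals at 95%. They treat loci, peaks, starts or models as independent draws, which neighbouring ones are not, and cover counting error only. The 11 gene lists (170 genes) were compared with 10000 random lists of the same size, matched on coding status and on 5 classes of length, and a percentile gives the share of random lists with a lower count, ties counted as 50%. For the widest H3K4me3 peaks, random lists were drawn from genes with a peak. H3K27ac peaks not wholly within 1 kb of a start or gene end were joined over gaps of up to 12.5 kb, ranked by summed width, and split where the scaled rank curve has slope 1. Peak width took the place of signal wherever a signal had been planned.

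The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The text names members of the lists it discusses, the 10 genes with the widest H3K4me3 peaks, the 10 highest stitched H3K27ac regions, the 10 genes with the most isoforms, and the 10 unannotated lncRNA loci with the highest TPM among those with a long-read intron and H3K4me3 at a start. Results of some genes that the rule names are not reported here. The lists were activated stellate cell and myofibroblast, stellate cell identity and quiescence, TGF-β pathway, mesenchymal transcription factor, ubiquitous, hepatocyte, cholangiocyte, endothelial, macrophage, lymphocyte and long noncoding RNA. Alternatives changed the window, the peak width, the required overlap, the loci counted and the range of the shifts.

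The shift test was tested on simulated data for the overlap of the marks, with 21135 simulated peaks and 5 runs for each planted share. Planted shares of 2%, 10% and 50% gave 1.88%, 10.0% and 50.1% above the shifts, each with p below 0.05 in 5 of 5 runs, and a planted share of 0 gave no such run. The simulated peaks that were not planted lay at random places. The runs therefore do not show how the shift test behaves for positions clustered near genes. Of 200 random gene lists with no effect, 7 lay in the upper and 5 in the lower tail of 2.5% each, and a planted list lay at percentile 100. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.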

Results

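Hepatic stellate cells are the vitamin A-storing pericytes of the liver, which become collagen-producing myofibroblasts in fibrosis and also during growth on plastic. Primary adult human stellate cells were grown untreated in medium with serum, and their transcripts and promoter and enhancer marks were catalogued. The series held 13 samples in 8 groups: 2 H3K4me3, 2 H3K27ac and 2 IgG CUT&Tag samples, 2 cytoplasmic and 2 nuclear RNA samples, and 1 sample each of poly(A) RNA, rRNA-depleted RNA and long-read poly(A) RNA. The IgG, cytoplasmic, nuclear and rRNA-depleted samples were not analysed here. H3K4me3 is a mark of active promoters and H3K27ac a mark of active promoters and enhancers. On chromosomes 1 to 22 and X, the H3K4me3 list held 21135 peaks with a median width of 674 bp, and the H3K27ac list 111572 peaks with a median width of 726 bp. They covered 21.5 Mb and 117 Mb. The long-read catalogue held 17672 transcripts in 7606 loci, with a median length of 1783 bases and a median of 7 exons. The long noncoding RNA (lncRNA) catalogue, assembled from short poly(A) reads, held 17607 models in 12395 loci, with a median length of 588 bases. Of these models, 43.4% had a single exon, against 6.86% of the long-read transcripts. Each mark had 1 list standing for 2 replicates and each transcript catalogue came from 1 sample, so no value has a spread between replicates. The number of reads behind each peak or long-read transcript is unknown. Exact Clopper-Pearson intervals are at 95% and cover counting error only, and genes, loci and peaks are not replicates.

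Genes of the activated stellate cell and myofibroblast were well represented in all 3 kinds of data. All 24 genes of that list had a long-read transcript, among them ACTA2 and TAGLN, the smooth muscle actin and transgelin of contractile cells, the fibrillar collagens COL1A1, COL1A2 and COL3A1, the matricellular protein gene CCN2 and the receptor PDGFRB. COL5A1 was the gene with single-exon transcripts only. Of the 24, 22 had an H3K4me3 peak and 22 an H3K27ac peak within 1 kb of an end of the annotated gene. The exceptions to both were POSTN, encoding the matrix protein periostin, with 5 isoforms, and THY1, a fibroblast surface antigen, with 7 isoforms. THY1 had peaks of both marks inside its interval, and POSTN had H3K27ac but no H3K4me3 there. Random lists matched on coding status and length held on average 8.68 genes with long reads, 13.9 with H3K4me3 and 16.3 with H3K27ac. The list lay at the percentiles 100, 99.99 and 99.6 of 10000 such lists.

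Genes tied to the quiescent stellate cell were sparser. Long-read transcripts were found for 4 of the 20 genes of the stellate cell identity and quiescence list: the transcription factor genes TCF21 and HAND2, the matrix gene ECM1 and BAMBI, a pseudoreceptor of TGF-β signalling. H3K4me3 marked 7 of them (the same 4, RGS5, PDGFRA and ADAMTS13), at percentile 2.51 of random lists, and the long-read count lay at percentile 7.21. H3K27ac was near 15 of the 20, at percentile 77.5. Neither mark was found within 1 kb of the ends of LRAT, which encodes the enzyme that esterifies retinol for storage, nor of GFAP, LHX2, RELN or PPARG. GFAP, LHX2, RELN and PPARG had H3K27ac but no H3K4me3 inside their intervals, and LRAT had neither mark there. HGF, DES, NGFR, NES, COLEC11, VIPR1 and CYGB were among the genes with H3K27ac but no H3K4me3 within 1 kb of an end. The file gives no read counts for long-read transcripts, so a gene without one was not detectable at an unknown depth.

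The TGF-β pathway and mesenchymal transcription factor lists were both well marked. In the TGF-β list, 12 of 18 genes had long reads (percentile 99.7), 16 had H3K4me3 (99.4) and 17 had H3K27ac (99.1). TGFBR3, a co-receptor, had neither mark at its ends, and INHBA, which encodes an activin subunit, had H3K27ac alone there, although both genes held H3K4me3 inside their intervals. SMAD4, SMAD7, SKI, TGFB3 and TGFBR1 had both marks and no long-read transcript, and SMAD3 and TGFBR2 had single-exon ones only. Among 20 mesenchymal transcription factor genes, 11 had long reads (percentile 98.0), 19 had H3K4me3 (100) and all 20 had H3K27ac (99.99). RUNX2 was the gene without H3K4me3 at its ends. GATA4, GATA6, TWIST1, PRRX1, TBX20, TEAD1, YAP1 and KLF4 carried both marks without a long-read transcript, and those of RUNX1 and SRF were single-exon. All 12 ubiquitous genes, such as GAPDH and ACTB, had all 3 readouts.

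Each list of other liver cells had fewer genes with each readout than random lists had on average, and the cholangiocyte list lay closest to them. None of the 12 hepatocyte genes, including ALB, APOA1 and HNF4A, had a long-read transcript (percentile 0.225), 1 had H3K4me3 (TF, encoding transferrin, percentile 0.055) and 4 had H3K27ac (1.47). None of the 8 lymphocyte genes had any of the 3 readouts within 1 kb of the gene ends, at percentiles 1.65 for long reads, 0.23 for H3K4me3 and 0.02 for H3K27ac. The macrophage list held CD14 and CD68 among its 10 genes with long reads (percentile 22.4), with H3K4me3 at 0 of 10 (0.04) and H3K27ac at 4 (9.79). The endothelial list held 1 long-read gene of 10, PECAM1, through a single-exon transcript (6.27), 1 gene with H3K4me3, KDR (0.145), and 4 with H3K27ac (4.31). The cholangiocyte list held 2 of 8 genes with long reads, among them the keratin gene KRT7 (percentile 34.8), KRT7 and SOX9 with H3K4me3 (8.77) and 4 genes with H3K27ac (27.7). Some of the counts of 0 to 2 in these lists moved by 1 gene with another peak rule or a stricter transcript match. A window of 2 kb took hepatocyte genes with H3K27ac from 4 to 8.

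**Figure D1:**
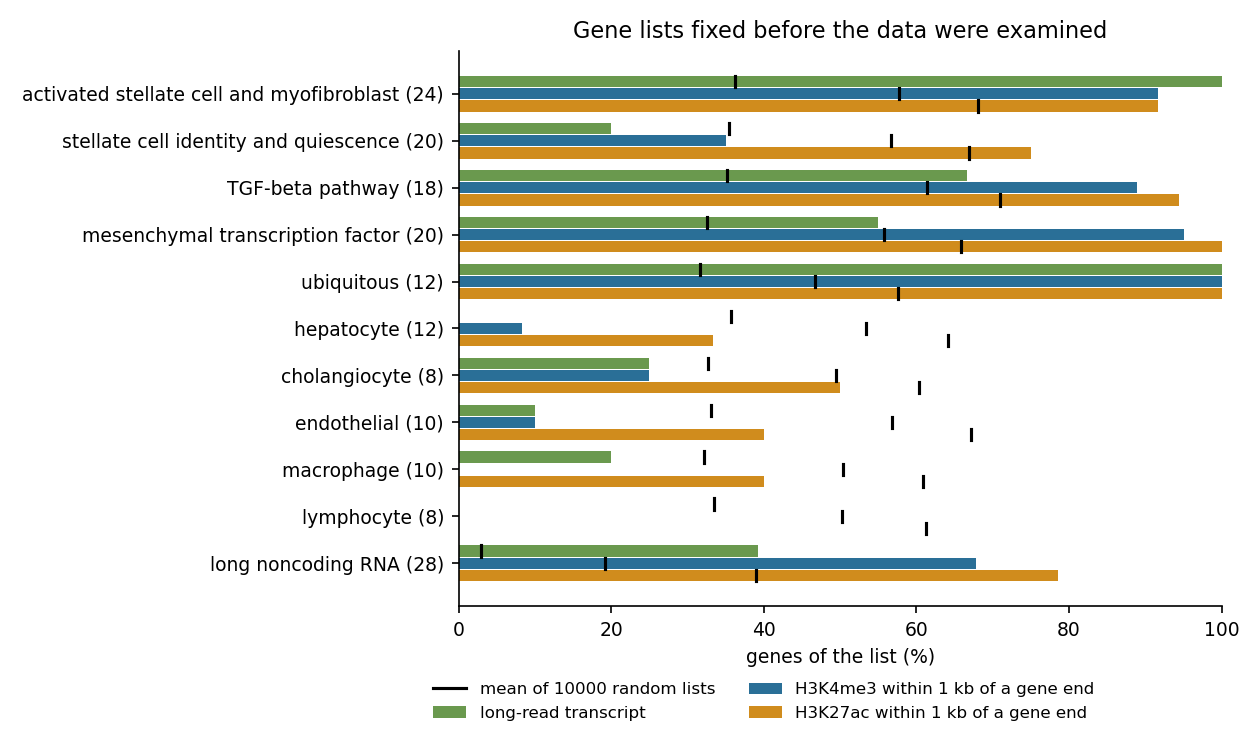
Share of genes (%, x axis) of each fixed list (y axis, number of genes in brackets) with a long-read transcript, an H3K4me3 peak or an H3K27ac peak within 1 kb of an end of the annotated gene; black ticks give the mean of 10000 random lists matched on coding status and length. The activated stellate cell list had long reads for 24 of 24 genes, and the hepatocyte list for 0 of 12.

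Genes of the extracellular matrix and the cytoskeleton had the most long-read isoforms, a measure of transcript structure that also depends on how deeply a gene was read. Among the 10 genes with the most, FN1, encoding fibronectin (chromosome 2, 215359483 to 215436068, GRCh38), had 132 isoforms with 115 distinct intron chains and COL1A1 (chromosome 17, 50184104 to 50201634) had 112. CCN2 followed with 74, the tissue plasminogen activator gene PLAT with 53, the actin gene ACTG1 with 52, the collagen cross-linking oxidase gene LOXL2 with 51, TAGLN with 50, ACTB with 46 and ACTA2 with 42. Of these genes, CCN2, FN1, COL1A1, LOXL2, TAGLN and ACTA2 are in the activated stellate cell list. Across the 7606 loci the median was 1 isoform, 3706 loci (48.7%) had at least 2 and 136 had at least 10.

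Protein-coding genes accounted for 7228 of the 7606 long-read loci. A further 253 lay in annotated lncRNA genes, 82 in pseudogenes and 41 in no annotated gene. Overlap of at least 1 exonic bp with an annotated gene of any class, on either strand, was found for 99.5% of loci (99.3 to 99.6). When transcript and gene had to share at least 50% of their joint span, a setting chosen after seeing the data, the share was 80.6%. Intron chains could not be matched to annotated chains, since the gene table used here has gene intervals without exons.

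Some genes had long-read starts in separate promoters. Of 6239 loci with a start inside an H3K4me3 peak, 100 (1.60%) had starts in at least 2 peaks, and in 63 the peaks were more than 5 kb apart. Named after their values were seen, ACTA2 had starts in 2 peaks 36.8 kb apart, ERCC1, a DNA repair gene, in 3 peaks with a largest gap of 52.9 kb, and TPM4, a tropomyosin gene, in 2 peaks 7.95 kb apart. The gap in LRRFIP1 was 63.2 kb.

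The widest H3K4me3 peaks lay over the starts of long-read transcripts or over ends of annotated genes. The widest, 10763 bp on chromosome 7 (5418486 to 5429248), lay over an end of TNRC18. It was followed by peaks over ACTG1 (8580 bp), BRD2, encoding a reader of acetylated histones (7888 bp), RUNX1-AS1 (6724 bp, inside the interval of RUNX1), PPP1R18 (6619 bp), LOC124903465 (6500 bp) and STX10 (6380 bp). VEGFA, the vascular growth factor gene, had 6148 bp, the homeobox gene MEIS1 6113 bp and PDGFRA, a platelet-derived growth factor receptor gene that had no long-read transcript, 6053 bp. All 10 overlapped H3K27ac peaks.

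The widest 5% were the 1058 peaks of at least 2724 bp. They lay over starts or ends of 11 of the 21 activated stellate cell genes with a peak there (percentile 99.995 of 10000 lists drawn from genes with a peak), among them COL1A1, COL5A1, LOX, SPARC and CDH11. The counts were 8 of 16 for mesenchymal transcription factors (99.985; FOXF1, GATA6, MEIS1 and NR2F2 among them), 5 of 11 for the TGF-β list (99.6) and 3 of 7 for the identity list (97.52; PDGFRA, BAMBI and HAND2). Ubiquitous genes were in them at 9 of 12 (100), and the long noncoding RNA list at 11 of 20 (100). The hepatocyte, cholangiocyte and endothelial lists each had 1 gene with a peak and 0 in the widest 5%, at percentiles 43.5, 43.7 and 44.1, while the macrophage and lymphocyte lists had no gene with a peak. Peak width was the only measure of size the lists gave.

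The largest clusters of H3K27ac peaks lay over genes such as GLI2, ERGIC1, SEPTIN9 and SMAD3. The 97632 peaks not wholly within 1 kb of a start or gene end, which include peaks that reach into such windows, were joined into 36694 regions, and 1642 of these (4.47%), each with at least 10.5 kb of peaks, lay past the tangent of the rank curve and held 30.6% of the acetylated bases. The first lay over GLI2, a hedgehog pathway transcription factor gene (chromosome 2, 120586823 to 120966910, 139 kb of peaks). The second, on chromosome 5 (172687882 to 172980286, 135 kb), ran over ERGIC1, RPL26L1 and the phosphatase gene DUSP1. SEPTIN9, PRKCH and MICAL2 followed, and SMAD3, a transducer of TGF-β signals, was sixth (chromosome 15, 67064907 to 67197724, 75.6 kb). SCIRT, ZMIZ1, AFAP1 and TNS1 completed the first 10.

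Of the activated stellate cell list, 15 of 24 genes overlapped these 1642 regions (2.26 on average in matched random lists, percentile 100), including LOXL2 (rank 23), TPM1 (25), COL1A1 (31) and COL6A3 (48). The TGF-β list had 10 of 18 (100), with SKI at rank 19 and the inhibitory SMAD7 at 28, and the mesenchymal transcription factor list 9 of 20 (99.995), with ETS1 at 44 and NR2F2 at 110. The identity list had 4 of 20 (93.4), namely HAND2, PDGFRA, CYGB and DES. Ubiquitous genes had 3 of 12 (97.6), cholangiocyte genes 2 of 8 (92.8; KRT7 and KRT19) and endothelial genes 1 of 10 (53.1; VWF). Hepatocyte (18.4), macrophage (21.3) and lymphocyte (25.5) genes had 0. The long noncoding RNA list had 11 of 28 (100), among them CARMN, a smooth muscle lncRNA, MIR100HG, PVT1 and NEAT1. Regions were ranked by summed peak width, since the list held no signal values, and an overlap does not assign a region to a gene.

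**Figure D2:**
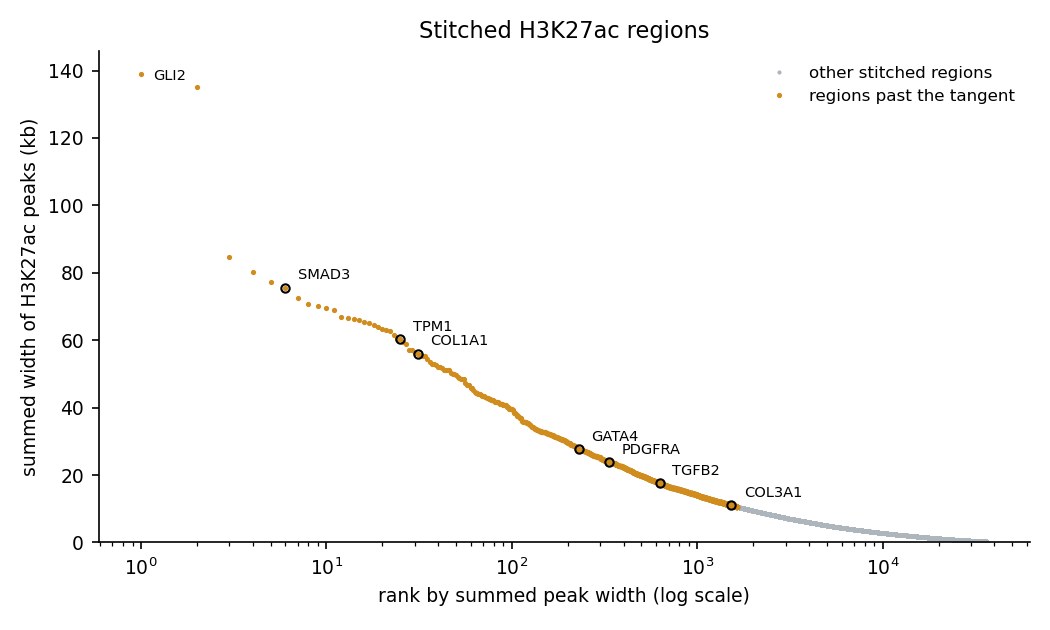
Summed width of H3K27ac peaks in kb (y axis) of 36694 stitched regions against their rank (x axis, log scale), with the 1642 regions past the tangent in orange, the others in grey, and open circles for the best region over each of 7 genes of the fixed lists. GLI2 held the first region with 139 kb and SMAD3 the sixth with 75.6 kb.

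Most H3K4me3 peaks overlapped H3K27ac peaks, and most H3K27ac peaks did not overlap H3K4me3. Of 21135 H3K4me3 peaks, 18368 (86.9%, 86.4 to 87.4) overlapped an H3K27ac peak by at least 1 bp, against a mean of 7.75% and a highest of 9.20% in 1000 circular shifts of positions within chromosomes (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The 2767 H3K4me3 peaks without H3K27ac were narrower, with a median of 282 bp against 880 bp. In the other direction 16336 of 111572 H3K27ac peaks (14.6%, 14.4 to 14.9) overlapped H3K4me3, against 1.45% in the shifts (permutation p = 0.001). These p-values are about the positions in these lists, not about other cells.

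A larger share of the H3K4me3 list than of the H3K27ac list lay at starts of deposited transcripts, although the H3K27ac peaks there were more numerous (14205 against 9426). Within 1 kb of a long-read or lncRNA start lay 44.6% of H3K4me3 peaks (43.9 to 45.3; shifted mean 2.26%, permutation p = 0.001) and 12.7% of H3K27ac peaks (shifted mean 2.07%, permutation p = 0.001). A further 4866 H3K4me3 peaks and 13334 H3K27ac peaks lay near an annotated gene end alone. The interior of annotated genes held 24.5% of H3K4me3 and 51.3% of H3K27ac peaks, and the space between genes 7.84% and 24.1%. H3K4me3 overlapped 59.3% of H3K27ac peaks at transcript starts, 5.28% of those inside genes and 3.71% of those between genes. The median H3K4me3 width was 1378 bp at transcript starts and 291 bp between genes.

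Most starts of long-read transcripts were marked by both modifications. Of 14200 distinct long-read starts, 88.2% (87.6 to 88.7) had H3K4me3 and 91.2% (90.7 to 91.7) had H3K27ac within 1 kb, against shifted means of 2.33% and 11.0% (permutation p = 0.001 for both). Starts in protein-coding genes had H3K4me3 in 89.0% of 13666 cases and starts in annotated lncRNA genes in 67.6% of 364 (adjusted exact p = 1.08e-26), and H3K27ac in 91.6% and 80.2% (adjusted exact p = 2.16e-11). Of the long-read loci in lncRNA genes, 92 of 253 were single-exon, against 604 of 7228 in protein-coding genes. The comparison was not made within exon classes. Of the 45 starts in no annotated gene, 51.1% (35.8 to 66.3) had H3K4me3 and 77.8% (62.9 to 88.8) had H3K27ac.

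Multi-exon transcripts had H3K4me3 at 92.6% of starts and H3K27ac at 94.5%, while single-exon transcripts had them at 36.1% and 52.2% (adjusted exact p = 8.81e-293 for H3K27ac). Starts inside a later exon of another transcript of the locus had H3K4me3 in 21.1% of 393 cases, against 90.1% of the others (adjusted exact p = 1.49e-216), and H3K27ac in 37.4% against 92.7% (adjusted exact p = 1.12e-163). The most upstream start of a locus was marked less often than the other starts, at 85.5% against 91.2% for H3K4me3 (adjusted exact p = 2.35e-26) and 89.0% against 93.7% for H3K27ac (adjusted exact p = 1.41e-22). These are two-sided Fisher's exact tests over starts, adjusted by Benjamini-Hochberg over 8 tests. The most upstream class takes in every start from a locus of 1 transcript. Such loci gave 55.0% of starts without H3K4me3 and 23.8% of those with it, so the order within a locus was not tested. Of the 1679 starts without H3K4me3, 42.0% were single-exon and 55.0% came from loci of 1 transcript. In this group 25.6% (23.5 to 27.8) lay more than 1 kb downstream of another start of their locus within that transcript, against 3.11% (2.82 to 3.43) of marked starts.

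The lncRNA catalogue ranged from abundant known transcripts to weak loci. MALAT1, a nuclear-retained lncRNA, had 628 TPM, GAS5, a host of small nucleolar RNAs, 443, CYTOR 181, MIR100HG 162, the imprinted MEG3 99.1 and SNHG1 46.7. CARMN had 20.6, LINC-PINT 10.5, GATA6-AS1 7.24, MIR503HG 6.89, PVT1 6.18, NEAT1 5.30, MIR31HG 3.28, DNM3OS 2.41 and FENDRR 2.18 TPM. H19 (0.786), LINC00973 (0.726), TGFB2-AS1 (0.226) and NORAD (0.203) were below 1 TPM. For NEAT1, a single-exon model on the opposite strand had 410 TPM, and for CARMN one opposite a long-read transcript had 97.1 TPM, while MALAT1 had no such model. In the long noncoding RNA list as a whole, 11 of 28 genes had long reads, 19 had H3K4me3 and 22 had H3K27ac at their ends (percentile 100 for each, against 0.809, 5.39 and 10.9 in random lists). H19, HOTAIR, HOTTIP, HOXD-AS2, MIR503HG and LINC00973 had none of the 3, although MIR503HG reached 6.89 TPM and LINC00973 had H3K27ac inside its interval and within 1 kb of a start of its lncRNA models. Only 5 of the 28 kept a long-read transcript when 50% of the joint span had to be shared.

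Of the 12395 lncRNA loci, 3710 (29.9%, 29.1 to 30.7) held a model with an Ensembl transcript identifier and are called annotated. The other 8685 (70.1%) are called unannotated, of which 2659 (30.6%) lay in a protein-coding gene interval, 2985 (34.4%) in another annotated gene interval only and 3041 (35.0%) in none. The annotated share was 43.2% among multi-exon loci and 55.8% among loci of at least 1 TPM, both sets chosen after seeing the data. Unannotated loci were single-exon in 67.7% of cases and annotated loci in 42.5%, and their median TPM was 0.270 against 0.548. Only 2453 loci (19.8%) reached 1 TPM. Of the 100 models with the highest TPM, 49 lay for at least 50% of their length opposite long-read exons, 73 had no Ensembl identifier, 70 were single-exon and 17 lay in pseudogenes. These 100 models held 51.9% of all TPM in the catalogue.

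A small share of the short-read lncRNA loci overlapped long-read transcripts, and the size of that share depended on strand. Of the 7606 long-read loci, 7228 lay in protein-coding genes and 253 in annotated lncRNA genes. A low overlap is therefore partly fixed by what the 2 catalogues hold, and a locus without overlap is not thereby refuted. Same-strand exonic overlap with a long-read transcript was found for 222 of 12395 loci (1.79%, 1.56 to 2.04). This was above the mean of circular shifts (1.40%, one-sided permutation p = 0.004) and below the mean of shifts by 10 kb to 1 Mb (2.16%, p = 0.995) that keep loci near genes, a setting added after seeing the data. With at least 50% of exonic bases overlapped the share was 1.11%, against 0.189% in circular and 0.327% in the nearer shifts (permutation p = 0.0476 for both, the smallest that 20 shifts can give). Among the upper 50% of loci by TPM it was 3.39%, against 1.73% (permutation p = 0.001) and 2.74% (permutation p = 0.003). Annotated loci overlapped in 181 cases (4.88%) and unannotated loci in 41 (0.472%), of which 2 were single-exon. On either strand, a count also added after seeing the data, 575 annotated (15.5%, 14.3 to 16.7) and 238 unannotated loci (2.74%, 2.41 to 3.11) overlapped, 160 of the latter single-exon. That was 6.56% of all loci, against 4.31% in the nearer shifts (permutation p = 0.001). An exact shared intron was found for 131 of 2135 annotated multi-exon loci (6.14%) and 25 of 2805 unannotated ones (0.891%; odds ratio 7.27, two-sided Fisher's exact p = 2.79e-26).

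Among the 8685 unannotated loci, 11 shared an intron with a long-read transcript and had H3K4me3 within 1 kb of a start, and the 10 with the highest TPM all had H3K27ac as well. The first, STAR.13914 on the minus strand of chromosome 5 (54660311 to 54703384), had 31.6 TPM, 3 exons and 2 shared introns and lay in the interval of LINC02998. STAR.44580 on chromosome 20 (30377181 to 30417820) had 3.67 TPM, up to 9 exons and 5 shared introns, in the pseudogene FRG1BP. STAR.39308 on chromosome 17 (30600830 to 30634162), in SMURF2P1-LRRC37BP1, had 3.48 TPM and 5 shared introns. STAR.23920 had 3.45 TPM in LOC107984035, STAR.34962 2.56 in LOC105376704, STAR.39650 2.07 in RARA-AS1 and STAR.43394 1.16 in the interval of IGSF23. STAR.24131 on chromosome 9 (66270028 to 66316270, 1.86 TPM) and STAR.38320 on chromosome 16 (86929624 to 86931404, 0.942 TPM) lay in no annotated gene. STAR.47003 on the X chromosome had 0.448 TPM, in LINC03112. An annotated gene interval here is of the RefSeq table, so these loci lack an Ensembl identifier in the file but are not all outside known genes.

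Promoter marks were more frequent at annotated than at unannotated spliced lncRNAs. Among multi-exon loci, H3K4me3 lay within 1 kb of a start in 57.4% of 2135 annotated loci (55.3 to 59.5) and 25.1% of 2805 unannotated loci (23.5 to 26.7; odds ratio 4.03, adjusted exact p = 2.12e-118). H3K27ac lay at 75.7% (73.9 to 77.5) and 60.8% (58.9 to 62.6; odds ratio 2.01, adjusted exact p = 7.22e-29). All 4 values lay above their shifted means of 3.04%, 2.17%, 13.9% and 11.0% (permutation p = 0.001). H3K27ac without H3K4me3 was found at 20.0% of the annotated and 37.0% of the unannotated multi-exon loci.

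Single-exon loci gave another picture. H3K4me3 was near 24.4% of 1575 annotated and 22.3% of 5880 unannotated single-exon loci (odds ratio 1.12, adjusted exact p = 0.0787). H3K27ac was near 39.0% and 76.1% (odds ratio 0.201, adjusted exact p = 3.87e-162), so that over all loci it was less frequent at annotated ones (60.1% against 71.1%, adjusted exact p = 2.79e-32), with H3K4me3 at 43.4% and 23.2% (odds ratio 2.54, adjusted exact p = 5.53e-109). The H3K27ac share of unannotated single-exon models had a step at 1 kb: the nearest peak lay 0.8 to 1 kb from the start in 458 models and 1 to 1.2 kb in 60 (88.4% on the inner side, 85.3 to 91.0). At the other end of these models the counts were 195 and 183 (51.6%, 46.4 to 56.7). Unannotated multi-exon models had 96 and 48 at the start (66.7%, 58.3 to 74.3) and 98 and 72 at the end (57.6%, 49.8 to 65.2), with overlapping intervals. At the starts of annotated multi-exon models the counts were 36 and 42 (46.2%, 34.8 to 57.8). Unannotated single-exon models kept for an H3K27ac peak within 1 kb of the start would give the step seen in them. Such a rule cannot have held for all of them, since 1326 of the 5880 loci (22.6%) had neither mark. The 76.1%, and the H3K27ac comparisons that include these models, may therefore be partly fixed by such a selection and decide nothing. The order of annotated and unannotated loci over all loci was not kept with the wider H3K27ac peaks (52.0% against 51.8%, exact p = 0.844) or with a 500 bp window (55.9% against 54.9%, exact p = 0.344).

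**Figure D3:**
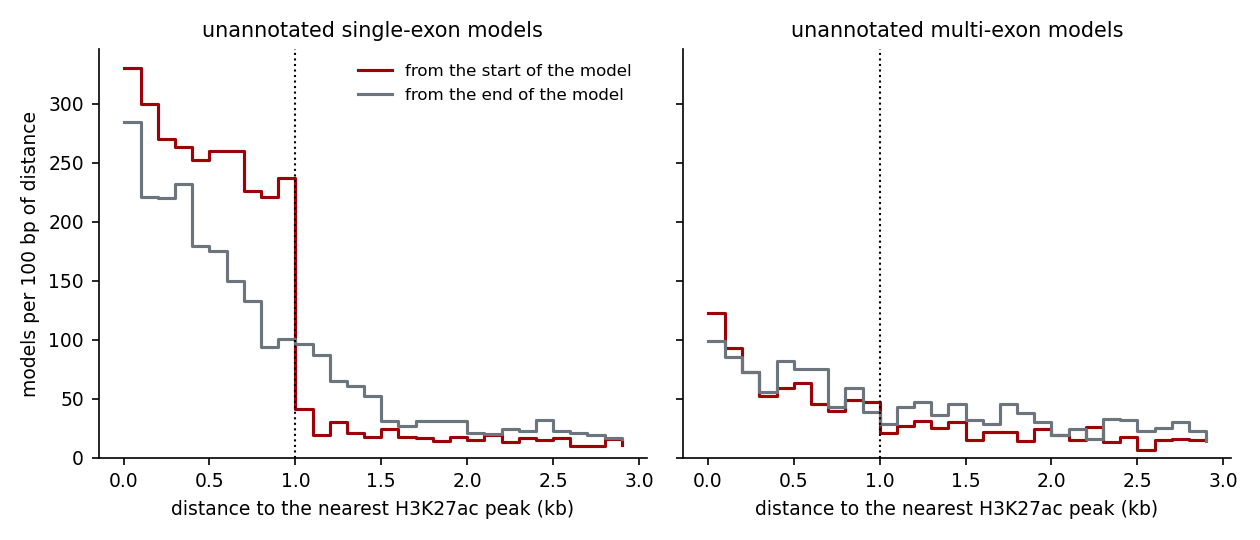
Number of unannotated lncRNA models per 100 bp of distance (y axis) by the distance in kb from their start (red) or end (grey) to the nearest H3K27ac peak (x axis; overlapping peaks not drawn), for single-exon (left) and multi-exon models (right), with a dotted line at 1 kb. Single-exon starts fell from 458 models at 0.8 to 1 kb to 60 at 1 to 1.2 kb, and their ends from 195 to 183.

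Strand and position also set the lncRNA loci apart. Over all 12395 loci, H3K4me3 was near 29.3% (28.5 to 30.1; shifted mean 2.31%, permutation p = 0.001) and H3K27ac near 67.8% (67.003 to 68.656; shifted mean 11.3%, permutation p = 0.001), a share that the step at 1 kb affects. Loci starting divergently within 1 kb of a long-read start had H3K4me3 in 97.1% of 622 cases and H3K27ac in 96.8%. These shares are partly fixed by position, since 88.2% of all long-read starts had H3K4me3 and 91.2% had H3K27ac. Loci opposite long-read exons had H3K4me3 and H3K27ac in 56.0% and 71.2%, loci in long-read introns in 19.9% and 43.6%, and loci apart from long-read transcripts in 23.1% and 66.5%. Among 8649 loci over 2 kb from coding ends and starts, 14.3% had H3K4me3 and 61.8% H3K27ac. Loci of at least 1 TPM had H3K4me3 in 50.6% of cases and weaker loci in 24.0% (odds ratio 3.24, adjusted exact p = 1.48e-137). For H3K27ac the shares were 70.2% and 67.2% (adjusted exact p = 0.00503). The H3K27ac shares by position, by distance from coding genes and by TPM include unannotated single-exon loci. The step at 1 kb may affect these shares too, so the H3K27ac comparison by TPM decides nothing.

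The strand of unannotated single-exon models went against the long reads. Of the 16 that overlapped exons of long-read transcripts outside annotated genes, 15 lay on the opposite strand (93.8%, 69.8 to 99.8), and of 13 multi-exon models 0 did. Where H3K4me3 was near 1 end only, it was the start in 31.3% of 434 unannotated single-exon models (upper bound 35.9), 86.9% of 839 unannotated multi-exon models, 98.0% of 2552 annotated multi-exon models and 81.9% of 149 annotated single-exon models. Starts and strands of single-exon models were used as the file gives them.

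**Figure D4:**
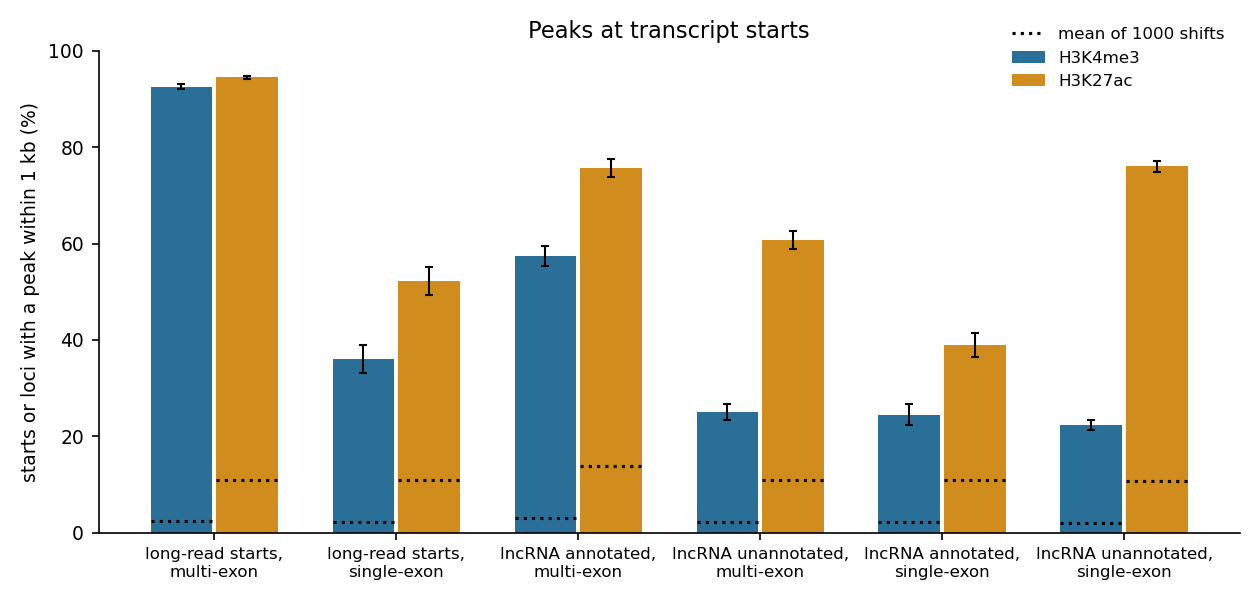
Share of long-read starts or lncRNA loci (%, y axis) with an H3K4me3 (blue) or H3K27ac (orange) peak within 1 kb, by class of transcript (x axis); error bars are exact 95% intervals for counting error and dotted lines the mean of 1000 shifts. H3K4me3 was near 92.6% of multi-exon long-read starts, 57.4% of annotated and 25.1% of unannotated multi-exon lncRNA loci.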

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

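The tests of mean isoforms of hosts, of strand outside annotated genes, of starts more than 1 kb downstream, of the step at 1 kb and of multi-exon models alone were chosen only after the results were seen. Signals outside the chromosomes used for the comparisons were above what a count of 0 allows. The long-read file held 115 transcripts on the mitochondrial chromosome and 23 on scaffolds, and the H3K27ac list held 328 peaks on scaffolds. No biological explanation was tested for any pattern below, since the design gives no groups to compare.

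Of the 100 lncRNA models with the highest TPM, 70 were single-exon, 49 lay opposite long-read exons (against 12.3% of the next 900 and 0.650% of the rest) and 40 were both. The planned test of abundant hosts, with isoforms as a stand-in for abundance, could not decide, because the central 95% of random medians ran only from 1 to 2 (hosts 2, n = 53), but the mean log2 number of isoforms was 1.24 in the hosts and 0.524 to 1.03 in the central 95% of 10000 random sets, as abundant hosts would give, although loci with more isoforms may also be overlapped more easily. Among models opposite long-read exons with H3K4me3 at 1 end only, 49.0% (34.8 to 63.4, n = 51) had it at their own start, as reads from the opposite strand of the host would give. That value pools single-exon models, with 21.7% (7.46 to 43.7), and multi-exon models, with 71.4% (51.3 to 86.8), so it speaks for such reads in single-exon models only. Unannotated single-exon models over long-read transcripts outside annotated genes lay on the opposite strand in 93.8% of 16 cases (69.8 to 99.8) and multi-exon models in 0 of 13. The strand of unspliced reads may therefore have been read opposite to the library, and true antisense RNA stays open. MALAT1 (628 TPM on its own strand) was an exception, but its locus is annotated, with models of up to 7 exons. Over long-read transcripts in no protein-coding gene, annotated single-exon models lay on the opposite strand in 25.7% of 35 cases. Unannotated single-exon models did so in 97.6% of 41.

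Long-read starts without H3K4me3 numbered 1679, of which 42.0% were single-exon and 41.9% had H3K27ac. The test planned for starts shortened at the 5′ end asked whether they lay downstream within another transcript of the locus more often than marked starts, and they did so less often (34.4%, 32.1 to 36.7, against 48.0%). That test could not decide, because a start within 1 kb of a marked start falls in the same window and counts as marked. At more than 1 kb downstream the order was the other way, 25.6% (23.5 to 27.8) against 3.11%, a measure also partly fixed by the window, so shortened cDNA may account for part of these starts. For the 55.0% from loci of 1 transcript nothing could be tested.

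H3K27ac lay near many unannotated lncRNA starts without H3K4me3, the arrangement of an enhancer. The planned tests compared starts with ends: among models with H3K27ac at 1 end only, 73.8% (71.5 to 75.9) had it at the start, and 78.8% (75.4 to 81.9) of single-exon models did. Both became void for single-exon models, because their starts showed a step at 1 kb. The share with a peak at 0.8 to 1 kb rather than 1 to 1.2 kb was 88.4% (85.3 to 91.0) at their starts and 51.6% at their ends. Models kept for an H3K27ac peak within 1 kb would give such a step. Not all can have been kept for it, since 22.6% of unannotated single-exon loci had neither mark. Multi-exon models had H3K27ac at the start in 70.4% (67.4 to 73.2) of cases with 1 marked end. Acetylated surroundings with no link to the start would give no such excess, but a selection for a peak at the start would. Such a selection of multi-exon models was not excluded, so the test could not decide. The share at 0.8 to 1 kb was 66.7% (58.3 to 74.3) at their starts and 57.6% (49.8 to 65.2) at their ends. At the starts of annotated multi-exon models it was 46.2% (34.8 to 57.8), an interval below that at the unannotated starts.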

How the results depend on the processing

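Shifts of 10 kb to 1 Mb, overlap on either strand or with the strand of unannotated single-exon loci turned, matches over 50% of the joint span, peaks anywhere over a gene, and counts of multi-exon loci or of loci of at least 1 TPM were chosen after seeing the data. No paired analysis was possible because each mark has 1 peak list for both replicates, with no values per replicate. Of 152 alternative values, 133 kept their direction and size or side of the threshold, 15 moved and 4 reversed; unless a construction is named, the cause was not tested. Most long-read loci lay in protein-coding genes, which partly fixes the overlap of a lncRNA catalogue with them. Long-read support of lncRNA loci stayed at 1.79% but fell below shifts of 10 kb to 1 Mb (2.16%, permutation p = 0.995), which keep loci near genes. It stayed above these shifts on either strand (6.56% against 4.31%), with the strand of unannotated single-exon loci turned (3.05% against 2.20%), with 50% of exonic bases (1.11% against 0.327%) and in the upper part by TPM (3.39% against 2.74%). For full intron chains (2.71%), counted among the 133, the shifts decide nothing, because exact introns cannot match after a shift. H3K27ac at annotated against unannotated loci was 52.0% against 51.8% with the wider peaks (exact p = 0.844), 55.9% against 54.9% in a 500 bp window (exact p = 0.344) and 75.7% against 60.8% in multi-exon loci (exact p = 5.41e-29). The annotated share of lncRNA loci was 73.6% by overlap with any gene interval on either strand, 43.2% in multi-exon loci and 55.8% in loci of at least 1 TPM. The share of long-read loci in annotated genes was 80.6% with 50% of the joint span. With peaks anywhere over the gene, H3K4me3 marked 2 hepatocyte and 2 endothelial genes, with the wider peaks 0 endothelial genes, and with a 2 kb window 1 macrophage and 1 lymphocyte gene. Multi-exon transcripts alone left 1 cholangiocyte and 0 endothelial genes with long reads, and the 50% match left 0 endothelial and 5 long noncoding RNA list genes. Of other counts, H3K27ac marked 8 hepatocyte genes with the 2 kb window and 1 endothelial gene with the wider peaks. Planned but not run, for lack of exons, sequence or signal, were exonic and intron matches of lncRNAs to the annotation, a 5 bp tolerance at splice sites, canonical introns, A-rich 3′ ends, starts inside annotated first exons and H3K4me3 ranked by signal. With no read counts, the depth behind an undetected transcript or peak is unknown.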

Other observations

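Spliced lncRNAs often started beside genes of the stellate cell programme, in a comparison chosen only after the results were seen. Of the multi-exon lncRNA loci, 595 had a long-read start on the opposite strand within 1 kb, 425 of them annotated and 170 unannotated. The pairs included developmental regulators: HOXB-AS1 (47.5 TPM) beside HOXB2 and HAND2-AS1 (chromosome 4, 173527270 to 173594553, 23.9 TPM) beside HAND2, a transcription factor gene of the stellate cell identity list. ZFAS1 (159 TPM) beside ZNFX1, SNHG1 (46.7 TPM) beside SLC3A2 and TPT1-AS1 (45.6 TPM) beside TPT1 were other abundant pairs. Among genes of the fixed lists, VIM was paired with VIM-AS1 (2.18 TPM), TCF21 with TARID (2.15), INHBA with INHBA-AS1 (0.293), TGFB2 with TGFB2-AS1 (0.226) and RPLP0 with PXN-AS1 (22.6). Each of the named lncRNAs had H3K4me3 and H3K27ac near its start except INHBA-AS1, which had H3K27ac alone.

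Spliced lncRNAs also started inside the large acetylated regions. Of the 1642 highest stitched H3K27ac regions, 508 (30.9%) held the start of a multi-exon lncRNA, and the most in a single region was 5. Annotated multi-exon loci started there in 273 of 2135 cases (12.8%, 11.4 to 14.3) and unannotated ones in 421 of 2805 (13.7 to 16.4%; odds ratio 0.830, two-sided Fisher's exact p = 0.0284, not adjusted). No set of random positions was drawn for these counts.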
